A study of Mus musculus with 4 samples.

How the data were processed

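RNA from lung tumors and from non-tumor lung of urethane-treated Nrf2+/+ and Nrf2-/- mice was pooled over 8 mice per group, per the labels' protocols, and 500 ng of each pool was labelled with Cy3 and hybridised to an Agilent whole-mouse-genome array (design 014868). Per the file headers, spots were read with Agilent Feature Extraction 10.7.3.1 and the array design was annotated on mouse build mm9. The deposited values are spot intensity on a linear scale: per the file headers, the processed signal is the brightness of the spot after subtraction of the background with spatial detrending and a multiplicative detrending step, and it carries an error estimate for each spot. Flags for background, saturation and uniformity came with each spot, per the file headers. No normalization between arrays is stated in the sources used here. The submitters' value table was set against the scanner signal of the same spots: each column equalled that array's processed signal on the linear scale within rounding, so it was neither logged nor centred, and its columns had medians of 79.2, 70.0, 47.2 and 50.1 in the group order used below. Groups were taken from the labels, which give 1 array per group. The labels number the arrays across groups, and these numbers pair nothing. It is not stated whether the tumors and the non-tumor lung came from the same animals.

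From these files the log2 of the processed signal was taken and each array's 75th percentile over non-control spots was subtracted; these percentiles were 760, 742, 555 and 584 intensity units for Nrf2+/+ non-tumor lung, Nrf2-/- non-tumor lung, Nrf2+/+ tumor and Nrf2-/- tumor. Spots of a probe were averaged, 245 probes having 10 spots each, and the median SD between replicate spots was between 0.07 and 0.08 on the log2 scale. The number of arrays limits the precision of every comparison. Of 41174 non-control probes, 4 with non-uniform spots were left out. Gene names came from a RefSeq table (assembly GRCm38.p6) matched on the accession of each probe without its version, or from the name in the file. Since that assembly differs from the build of the array, no coordinates are given and the table served only for names and gene order. A symbol was found for 26686 probes and none for 14484, and the latter were counted by their file name and not named. This gave 32300 genes or transcripts, of which 6829 had more than 1 probe, and each was represented by the probe with the highest mean level over the 4 arrays.

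Differences between 2 arrays were counted at a 2-fold mark among genes well above background on at least 1 of the 2 arrays. List members were counted if well above background on at least 1 of the 4 arrays. A counted member can therefore be below it on both arrays compared. The differences carry no test. The error beside them is the software's own. Slides were read from the file headers: slide 1 held 1 array and slide 2 held 3. A fit with slide as a block leaves no residual degree of freedom and was not run as a test, since its tumor coefficient equals the Nrf2-/- tumor difference and its genotype coefficient the tumor genotype difference, which are given. The single test was an additive fit (tissue plus genotype) with limma 3.58.1 in R 4.3.3, moderated with eBayes (prior degrees of freedom 2.18) and adjusted by Benjamini and Hochberg over 20553 genes, with a threshold of 0.05. The other steps used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9.

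The genes named were those with a symbol and the 8 largest differences each way per comparison among genes well above background on both arrays, the 3 largest lower bounds each way among genes not well above background on one array, the 8 each way that were largest in both genotypes or both tissues, and the 5 each way for the difference of differences, 87 genes in all; some results for single genes are not reported here. Members of gene lists were also named as examples, after their values were seen. The 27 lists covered Nrf2 target genes, cell cycle and proliferation, alveolar type 2, alveolar type 1, club, ciliated, endothelial, fibroblast, smooth muscle, cardiac muscle, macrophage, T and NK, B and plasma, neutrophil, adipocyte, mesothelial and erythroid markers, inflammatory cytokines and chemokines, interferon response, MHC class II presentation, Ras and MAPK pathway output, tumor-associated epithelial and invasion genes, hypoxia and glycolysis, fatty acid and sterol synthesis, cytochrome P450 and flavin monooxygenase genes, p53 response and reference genes. Some genes stand in more than 1 list. Each list's median was placed among 10000 random lists of the same size matched on mean level in 20 bins, as a description of these arrays, and lists outside the percentiles 2.5 to 97.5 were treated as standing apart. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except scaling on 7 bright spike-in probes, which was chosen after seeing the data.

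The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling on the array median, the mean of all probes of a gene, the submitters' value table, stricter and no filters on dim probes, a 3-fold mark, an intensity trend in eBayes, leaving out the other factor, leaving out each array in turn, and list medians over genes on all 4 arrays. Normexp had been planned on the mean spot signal and was run on the median spot signal and the median local background.

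The additive fit was tested on simulated data in 5 runs per setting, each with 200 genes changed for tissue and 200 others for genotype. With the spread of the 20553 genes tested, simulated for as many genes, it recovered 0 of the genes changed by 0.5, 1, 2 or 3 on the log2 scale, and 5.52% of unchanged genes lay past 2-fold between 2 arrays. With the spread of the 16287 genes on all 4 arrays, again simulated for as many genes, it recovered 0.8% of tissue changes of 0.5, 24.0% of those of 1, 97.6% of those of 2 and 100% of those of 3, and for genotype 0.4%, 27.2%, 98.4% and 99.6%, with 14 and 13.6 false calls per run, a larger share of the calls than the threshold allows, and 1.08% of unchanged genes lay past 2-fold.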

Results

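Gene expression was measured in urethane-induced lung tumors and in non-tumor lung of female ICR mice that carried the transcription factor gene Nrf2 (Nfe2l2; Nrf2+/+) or lacked it (Nrf2-/-). Urethane (ethyl carbamate) is a carcinogen that gives lung adenomas in mice. The animals, aged 6 months, had received 1 g/kg by intraperitoneal injection 16 weeks earlier, and the tumors taken were between 1.0 and 1.5 mm across. The design had 4 groups (Nrf2+/+ non-tumor lung, Nrf2-/- non-tumor lung, Nrf2+/+ tumor and Nrf2-/- tumor) with 1 whole-genome array each, hybridised with RNA pooled from 8 mice. There were therefore no replicates, no comparison between 2 arrays carries a p-value, and each difference below describes a pair of pools. The arrays were of similar quality: 63.5% and 62.1% of spots were well above background on the Nrf2+/+ and Nrf2-/- non-tumor arrays and 56.2% and 54.2% on the Nrf2+/+ and Nrf2-/- tumor arrays, with median signals of 79.2, 70.0, 47.2 and 50.1 intensity units. No spot was saturated. The scanner software's own error of a difference between bright spots was 0.20 on the log2 scale, which covers measurement only. The Nrf2+/+ non-tumor array lay on a slide of its own and the other 3 arrays shared a second slide, so the Nrf2+/+ tumor comparison and the non-tumor genotype comparison crossed slides, whereas the Nrf2-/- tumor comparison and the tumor genotype comparison lay within a slide.

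The targeted gene was examined first. Nfe2l2, which encodes the transcription factor that drives detoxification and antioxidant genes, had a signal of 7913 in Nrf2+/+ non-tumor lung and 7478 in Nrf2+/+ tumor. In both Nrf2-/- pools it was not well above background, with signals of 5.13 in non-tumor lung and 6.94 in tumor, which put it at least 376-fold lower in Nrf2-/- non-tumor lung and at least 268-fold lower in Nrf2-/- tumor. A fold given as "at least" sets the measured level on the brighter array against the dimmest level that was still well above background on the other array, or against the gene's own level there where that was higher. Both probes of the gene were low in both Nrf2-/- pools; where the probes lie relative to the deleted part was not given in the sources used here.

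The first comparison asked which genes were expressed at other levels in tumors than in non-tumor lung of Nrf2+/+ mice. Among genes measured in both tissues, Cyp2c40, a cytochrome P450 of fatty acid metabolism, was higher in tumor by 7.56 on the log2 scale, Cd177, a surface glycoprotein of neutrophils, by 6.93, and Alb, the plasma protein albumin, by 5.47. The noncoding RNAs Rian (6.28) and Meg3 (6.18) and the protein-coding gene Dlk1 (at least 72.3-fold), which belong to a common imprinted domain, were all higher in tumor. Fetub (5.85), Mogat2 (4.79) and Xlr3c (4.62) followed. Genes that were not well above background in non-tumor lung included Gkn2, a secreted protein of the stomach lining, at least 220-fold higher in tumor, the tight-junction gene Cldn2, at least 160-fold higher, and Cltrn, at least 128-fold higher. The largest lower values among genes with a symbol measured in both tissues belonged to Wif1, a secreted inhibitor of Wnt signalling (-4.07), and to muscle genes: Ckmt2, the mitochondrial creatine kinase of striated muscle (-3.73), Mybphl (-3.46), Csrp3 (-3.11), myoglobin (Mb, -3.07) and sarcolipin (Sln, -3.04). Rgs18 (-3.32) and Alpi (-3.25) lay in the same range. Against the same Nrf2+/+ non-tumor array, Wif1 (-4.30) and Alpi (-2.86) were also lower in Nrf2-/- non-tumor lung. Cfd, which encodes adipsin and was not well above background in tumor, was at least 22.8-fold lower in tumor, Tmem14c at least 17.1-fold and Myoz2, a sarcomere protein, at least 14.9-fold.

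The gene lists gave a picture by cell type in Nrf2+/+ tumors. Alveolar type 2 markers had a median difference of 1.17, with 14 of 18 measured members at least 2-fold higher and 1 lower. Among them were Muc1 (2.15), Abca3, a transporter of surfactant lipids (1.55), and Sftpb, a surfactant protein (1.51), whereas Chia1 was lower (-2.08). Alveolar type 1 markers had a median of -1.21, with 10 of 17 at least 2-fold lower, such as Hopx (-1.79) and Pdpn (-1.39), although Aqp5 stood at 0.70. All 18 ciliated cell markers were at least 2-fold lower (median -2.08), including Foxj1, the regulator of motile cilia (-2.24), and 17 of 22 endothelial markers were (median -1.38), including Tek (-2.09) and Pecam1 (-1.83). Cardiac muscle markers had a median of -2.70 (11 of 13 lower), mesothelial markers -1.60 (8 of 8 lower) and smooth muscle markers -1.08 (6 of 11 lower). Fibroblast and matrix markers had a median of -0.49 (7 of 21 lower, none higher), with Tcf21 at -2.20 and Col1a1 at 0.52. Club cell markers had a median of -0.53 (1 higher and 5 lower of 11). Erythroid genes had a median of -0.71 (2 of 6 lower). Each of these medians lay outside the central 95% of 10000 random lists matched on level; for the type 2, type 1, ciliated, endothelial and cardiac lists no random list reached as far.

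Pathway lists differed as well in Nrf2+/+ tumors. Of 30 cell cycle genes, 17 were at least 2-fold higher and none lower (median 1.10), among them Cdk1, the kinase that drives entry into mitosis (1.74), Ccnb1 (1.68) and Mki67 (1.10). Genes that report Ras and MAPK signalling had a median of 1.00, with 11 of 23 higher, led by the transcription factor Etv4 (at least 41.6-fold) and including the growth factor Areg (2.89), the phosphatase Dusp4 (2.33) and Spry2 (1.40), while Jun stood at -0.94. MHC class II genes had a median of 0.89 (3 of 8 higher, 1 lower), and hypoxia and glycolysis genes 0.51 (6 of 20 higher, 3 lower), with Ldha at 1.84 and Hk2 at 1.68 but Vegfa at -1.17. Among tumor-associated epithelial and invasion genes (median 0.34, 12 higher and 6 lower of 37) were Afp (3.32), Krt18 (1.75) and, lower, Zeb1 (-1.56). Sox9, a transcription factor of lung progenitors, was at least 55.4-fold higher by the probe used, while another of its 3 probes was below background on every array. Cytochrome P450 and flavin monooxygenase genes had a median of -1.58 (1 higher, 12 lower of 19), with Cyp2a5 at -2.24 and Cyp1b1 at 2.08. Macrophage markers had a median of 0.68 (8 higher, 3 lower of 23), with Arg1 at 2.70 and Marco at -1.61. The other leukocyte lists were lower: T and NK cell markers by a median of -0.81 (7 of 17 lower), B and plasma cell markers -1.13 (7 of 13) and neutrophil markers -1.14 (7 of 13). Interferon response genes had a median of -0.92 (6 of 16 lower), adipocyte markers -1.65 (1 higher, 5 lower of 8) and inflammatory cytokines and chemokines 0.40 (8 higher, 3 lower of 25), with Cxcl3 at least 43.1-fold and Cxcl5, which attracts neutrophils, at 2.85. Nrf2 target genes had a median of 0.40 (8 higher, 3 lower of 37), with Me1, malic enzyme, at 2.34 and Nqo1 at -1.64. Reference genes had a median of 0.27, Gapdh at 1.22 and Actb at 0.11, with 1 of 12 past 2-fold; among the lists of this paragraph theirs alone had a median within the central 95% of random lists. The Nrf2 target and the hypoxia and glycolysis medians also came within it with quantile normalization, the first also with the mean of all probes of a gene, and the tumor-associated median did over genes on all 4 arrays.

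In total, 1608 genes were at least 2-fold higher and 3052 at least 2-fold lower in Nrf2+/+ tumor among 19913 measured, which was 23.4%; the robust spread of all differences was 0.71 on the log2 scale. The balance of the directions depended on scaling and background correction. Higher genes made up 34.5% of those past 2-fold in the main setting and 55.1% (2633 higher, 2146 lower) when arrays were scaled on their medians. They made up 47.8% (1098 and 1198) after normexp background correction and 23.2% (1180 and 3915) when arrays were scaled on spike-in probes. These alternatives moved the median of all genes by 0.29, 0.11 and -0.21, in that order.

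In Nrf2-/- mice tumor and non-tumor lung were compared within a slide. Cd177 was higher in tumor by 6.72, Meg3 by 5.85, Fetub by 5.50, Cyp2c40 by 4.76 and Alb by 3.23. Ceacam10 (6.90), Serpinb5, a serpin of epithelial cells (6.61), Gkn2 (6.42) and Ubd, a ubiquitin-like protein induced by inflammatory cytokines (5.87), were among the highest. Cldn2 was at least 110-fold higher, Cltrn at least 75.8-fold and Dlk1 at least 68.8-fold. Nppa, which encodes atrial natriuretic peptide, was higher by 5.98, whereas the other cardiac markers in the list were lower. Among the lowest values were those of xenobiotic-metabolising genes, Cyp2a4 (-3.67), Cyp2a5 (-3.43) and Pon1 (-3.42), and of genes of muscle and motile cilia, Myl7 (-3.29), Tmem212 (-3.25), Foxj1 (-3.22) and Cfap161 (-3.21). Among genes not well above background in the tumor, Stk33 was at least 10-fold lower, Dnah5, a ciliary dynein chain, at least 9.79-fold and Ccdc81 at least 9.29-fold.

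By list, Nrf2-/- tumors had type 2 markers at a median of 0.98 (9 of 18 at least 2-fold higher, 1 lower) and type 1 markers at -0.82 (6 of 17 lower). Ciliated markers stood at -2.78 (17 of 18 lower), club cell markers at -1.09 (2 higher, 6 lower of 11) with Cyp2f2 at -2.48 and Scgb1a1, the main secretoglobin of club cells, at -1.24, and endothelial markers at -0.96 (10 of 22 lower). Cardiac muscle markers had a median of -2.35 (1 higher, 11 lower of 13), smooth muscle markers -1.49 (8 of 11 lower), mesothelial markers -1.52 (7 of 8 lower), fibroblast markers -0.40 (4 of 21 lower) and erythroid genes -1.06 (3 of 6 lower). None of the 30 cell cycle genes was past 2-fold in either direction. Their median of 0.29 lay above the central 95% of random lists, with 26 of 30 members above 0. It became -0.0045 with spike-in scaling, which moved the median of all genes by -0.29. Cdk1 stood at 0.60 and Mki67 at 0.25. Ras and MAPK genes had a median of 0.70 (7 of 23 higher), with Areg at 3.24 and Etv4 at 4.05, inflammatory cytokines 0.67 (8 higher, 2 lower of 25), with Cxcl9 at 3.05 and Ccl20 at 2.66, and macrophage markers 0.66 (2 higher, 1 lower of 23). MHC class II genes had a median of 0.67 with none past 2-fold, hypoxia and glycolysis genes 0.39 (3 of 20 higher), tumor-associated genes 0.51 (11 higher, 4 lower of 37) and P450 and flavin monooxygenase genes -0.91 (2 higher, 8 lower of 19). T and NK cell markers had a median of -0.36 (3 of 17 lower), which came within the central 95% of random lists with the mean of all probes of a gene. The medians of B and plasma cell markers (-0.17), neutrophil markers (-0.20), interferon genes (-0.17) and adipocyte markers (-0.19) lay within the central 95% of random lists. Nrf2 target genes had a median of 0.30 (7 higher, 3 lower of 37), with Me1 at 2.42 and Gsta1, a glutathione transferase, at least 4.26-fold lower in tumor; the list came within the central 95% of random lists with quantile normalization. Reference genes had a median of 0.30, within that range, with 1 of 12 higher.

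Counted over 19425 genes, 1055 were at least 2-fold higher and 1772 lower in Nrf2-/- tumor (14.6%, robust spread 0.48). Higher genes made up 37.3% of these in the main setting, 48.1% (1314 and 1417) with median scaling, 58.5% (733 and 519) with normexp and 20.8% (733 and 2788) with spike-in scaling; median and spike-in scaling moved the median of all genes by 0.14 and -0.29.

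**Figure D1:**
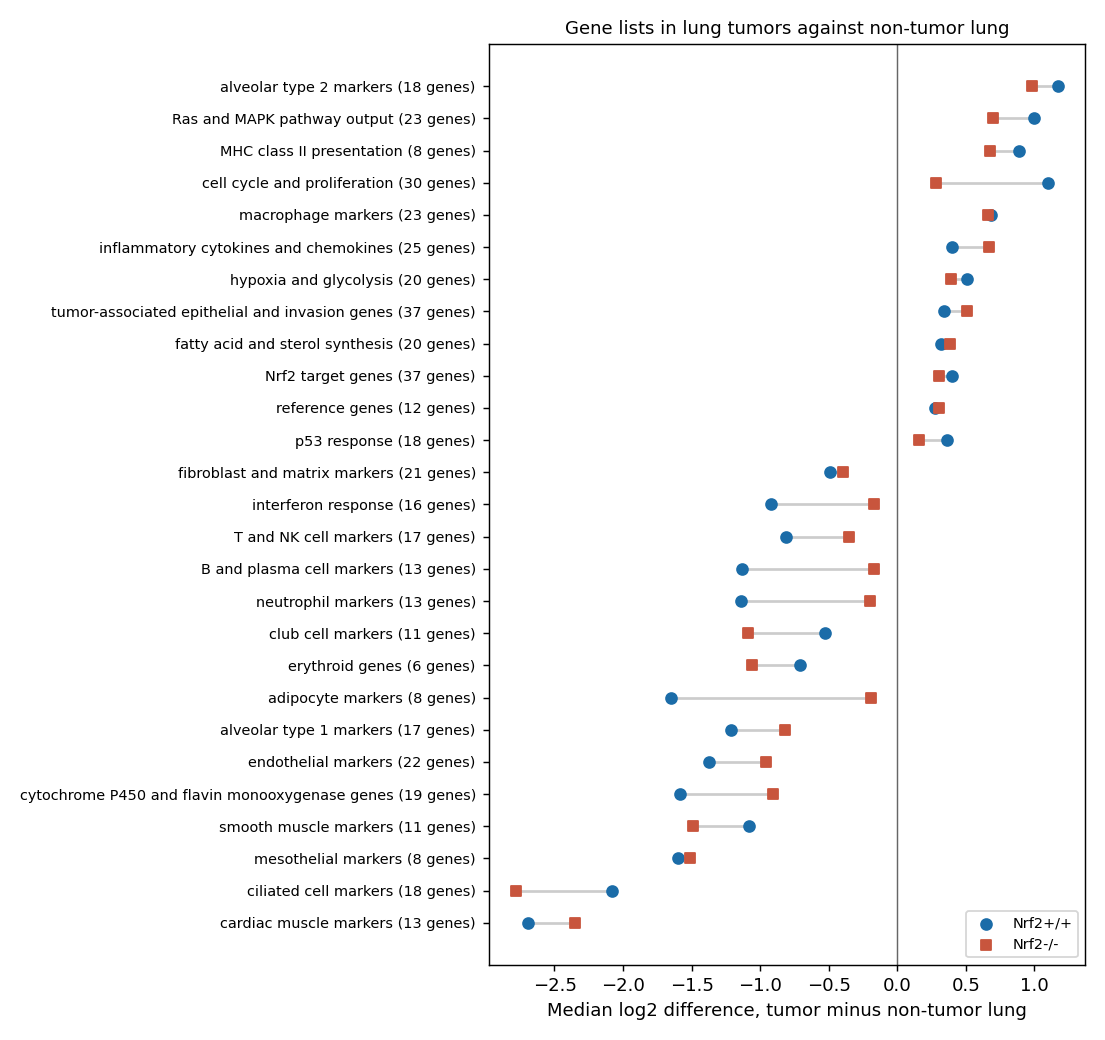
Median log2 difference, tumor minus non-tumor lung, of each gene list on the horizontal axis, with a point for Nrf2+/+ and a point for Nrf2-/- mice and 1 array per group. Ciliated cell markers lie lowest in Nrf2-/- mice at -2.78 and cell cycle genes stand at 1.10 in Nrf2+/+ against 0.29 in Nrf2-/- mice. The last of these became -0.0045 with spike-in scaling, which moved the median of all genes in Nrf2-/- mice by -0.29.

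Tumor differences were then set side by side between the genotypes, a pair of comparisons that shared no array. Among genes with a symbol that were well above background on all 4 arrays, those highest in tumors of both genotypes besides Cd177, Meg3, Fetub and Cyp2c40 were St8sia6, a sialyltransferase (4.42 in Nrf2+/+ and 4.93 in Nrf2-/-), Tmem213 (4.41 and 5.34), Bcl2l15 (4.36 and 4.90) and Cela1 (4.35 and 4.63). Among the lowest in both were striated muscle genes, Csrp3 (-3.11 and -3.08), Ckmt2 (-3.73 and -2.73), Tcap (-2.62 and -2.87), titin (Ttn, -2.52 and -2.48) and cardiac troponin T (Tnnt2, -2.48 and -2.80). Of 18785 genes measured in both, 659 were at least 2-fold higher and 1254 at least 2-fold lower in both genotypes, where independent lists of these sizes would share 68.9 and 207, and 39 were past 2-fold in opposite directions (239 if independent). The counts higher and lower in both were 912 and 885 with median scaling, 458 and 431 with normexp and 404 and 1995 with spike-in scaling. Across the 16287 genes well above background on all 4 arrays, Pearson's r was 0.80 and Spearman's rho 0.78; these are correlations across genes, which are not independent replicates.

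**Figure D2:**
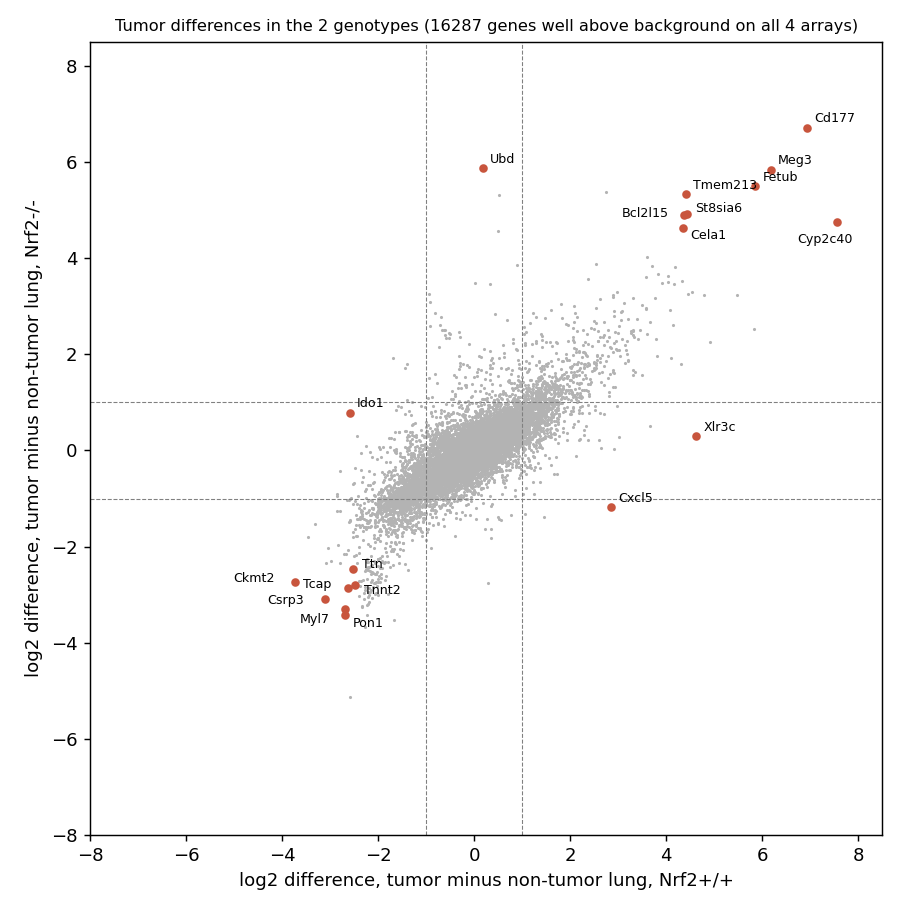
Log2 difference between tumor and non-tumor lung in Nrf2+/+ mice (horizontal axis) against that in Nrf2-/- mice (vertical axis) for each of 16287 genes, with dashed lines at 2-fold and named genes in red. Cd177 lies at 6.93 and 6.72, Pon1 at -2.68 and -3.42, and Cxcl5 at 2.85 and -1.18.

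The third comparison asked how non-tumor lung differed between genotypes. Genes of the Nrf2 target list were lower in Nrf2-/- lung: 7 of 37 were at least 2-fold lower and none higher (median -0.29, reached by none of 10000 random lists). Among them were Gpx2, a glutathione peroxidase (-2.08), Nqo1, the quinone reductase used as a standard readout of Nrf2 (-1.62), Aox1 (-1.61), Me1 (-1.30), Gstm3 (-1.19) and Gsta3 (-1.10), both glutathione transferases, and Gsr, glutathione reductase (-1.03). Txnrd1 (-0.77), Gclc (-0.37) and Hmox1 (0.14) did not pass 2-fold. Inflammatory cytokines and chemokines were higher, with 11 of 25 past 2-fold and none lower (median 0.89), including Ccl17, which attracts T cells (2.93), the monocyte attractants Ccl7 (1.87) and Ccl2 (1.79), and Cxcl1, at least 11.1-fold higher. Mesothelial markers had a median of 1.06 (4 of 8 higher), with Lrrn4 at 1.43 and Upk3b at 1.23, and macrophage markers a median of 0.60 (5 of 23 higher, 1 lower), with Ctsk at 2.13, Trem2 at 1.61 and Arg1 at -1.30.

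Among genes with a symbol measured on both arrays, the highest in Nrf2-/- non-tumor lung besides Ccl17 were Tescl (5.27), Pigs (3.21), Rgs16 (3.08), the mitochondrial peptidase Pitrm1 (3.01), Prg4, lubricin (2.88), Camk2n1 (2.87) and the hyaluronan synthase Has1 (2.80). Psca was at least 11-fold and the cell cycle inhibitor gene Cdkn2a at least 9.32-fold higher. The other probe of Pigs read 0.27. The lowest genes with a symbol measured on both arrays were Cdh1, which encodes E-cadherin (-5.01), Rmnd1 (-4.37), Wif1 (-4.30), the interferon-inducible GTPase Ifi47 (-4.25), the noncoding RNA Firre (-3.99), complement C3 (-3.60), Ido1 (-2.90) and Alpi (-2.86). Cdh1, Ifi47 and Firre had no other probe bright enough to compare in both tissues, so their values were not checked on another probe. Ces1f was at least 25.4-fold and Pawr at least 11.1-fold lower. Wif1 and Alpi were also among the lowest in Nrf2+/+ tumor (-4.07 and -3.25). Both comparisons use the Nrf2+/+ non-tumor array, so these values are not independent. Of the remaining lists, type 2 markers (median 0.31), T and NK cell markers (0.31), cell cycle genes (0.22), MHC class II genes (0.30) and tumor-associated genes (0.27, 6 higher and 3 lower of 37, from Timp1 at 2.58 to Cdh1) lay above the central 95% of random lists. B and plasma cell markers (-0.46), adipocyte markers (-0.51), neutrophil markers (-0.31), ciliated markers (-0.27), interferon genes (-0.26), P450 genes (-0.25) and club cell markers (-0.20) lay below it. Endothelial markers did too at -0.13, a median that became 0.0096 with median scaling. Fibroblast (0.09), Ras and MAPK (0.09), hypoxia and glycolysis (0.08), type 1 (0.02), reference (-0.02), cardiac (-0.10), erythroid (-0.11) and smooth muscle (-0.13) genes had medians within it, and with normexp so did the T and NK, P450 and club cell lists. In all, 614 genes were at least 2-fold higher and 931 lower of 20190 measured (7.65%, robust spread 0.33). Normexp left 204 and 255, and the filter on every array 328 and 465. Higher genes made up 39.7% in the main setting, against 51.6% (797 and 749) with median scaling, which moved the median of all genes by 0.14. This comparison crossed slides, so slide and genotype cannot be told apart in it.

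The fourth comparison set Nrf2-/- tumors against Nrf2+/+ tumors within a slide. Nrf2 targets were again lower, 8 of 37 past 2-fold and none higher (median -0.34, reached by no random list): Gsta1 at least 3.92-fold, Gpx2 -2.93, Gstm3 -1.49, Gsta3 -1.41, Gstm1 -1.34, Me1 -1.22 and Aox1 -1.22, while Gclc stood at 0.45 and Slc7a11 at 0.01. Inflammatory cytokines were higher, 14 of 25 past 2-fold (median 1.28), including Ccl3 (2.86), Cxcl13, a B-cell attractant (2.36), Cxcl9 (2.30), Ccl20 (2.26) and Ccl17 (2.22); Cxcl5 was the member 2-fold lower (-2.0). Cell cycle genes had a median of -0.53, reached by no random list, with 2 of 30 at least 2-fold lower, Ube2c (-1.03) and Cdk1 (-1.03), and none higher; Top2a stood at -0.96 and Ccna2 at -0.87. Ciliated markers had a median of -1.0 (9 of 18 lower), club cell markers -0.91 (1 higher, 4 lower of 11), with Cyp2f2 at -1.36 and the mucin gene Muc5b at 2.09, and smooth muscle markers -0.58 (1 of 11 lower).

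Among genes with a symbol measured on both arrays, the highest in Nrf2-/- tumors were Ptprn (5.02), the fibrinogen chains Fgg (5.0) and Fga (4.89), Ly6d (4.07), Ly6f (3.73), Hepacam (3.64), the non-classical class I gene H2-T23 (3.59) and Ubd (3.39). Among genes not well above background in Nrf2+/+ tumors, Tmem14c was at least 55.8-fold, Nppa at least 54.0-fold and Tescl at least 53.3-fold higher. Among the lowest were Rmnd1 (-4.55), Sox9 (-4.45), Firre (-4.43), C3 (-3.95), Bex2 (-3.62), Ifi47 (-3.32) and Bex1 (-3.30), and Cdh1 was at least 70.5-fold and Raet1e, a stress-induced ligand of NK cells, at least 42.1-fold lower. The remaining lists above the central 95% of random lists were adipocyte markers (0.91, with Cfd at least 10.2-fold higher), mesothelial markers (0.80), T and NK cell markers (0.68), interferon genes (0.56), macrophage markers (0.50), B and plasma cell markers (0.48), fibroblast markers (0.40), endothelial markers (0.34), neutrophil markers (0.31), type 1 markers (0.27), fatty acid and sterol synthesis genes (0.15), tumor-associated genes (0.27) and cardiac markers (0.21, but within it with normexp, with quantile normalization and over genes on all 4 arrays). Erythroid genes lay below it (-0.32). The medians of type 2 markers (-0.01), MHC class II genes (0.07), Ras and MAPK genes (-0.05), hypoxia and glycolysis genes (0.02), P450 genes (0.16) and reference genes (-0.07) lay within it. In all, 764 genes were at least 2-fold higher and 655 lower of 17824 (7.96%, robust spread 0.31), a main split of 53.8% higher. Normexp left 364 higher and 236 lower. With spike-in scaling, which moved the median of all genes by -0.12, the balance turned to 659 higher and 795 lower (45.3% higher).

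**Figure D3:**
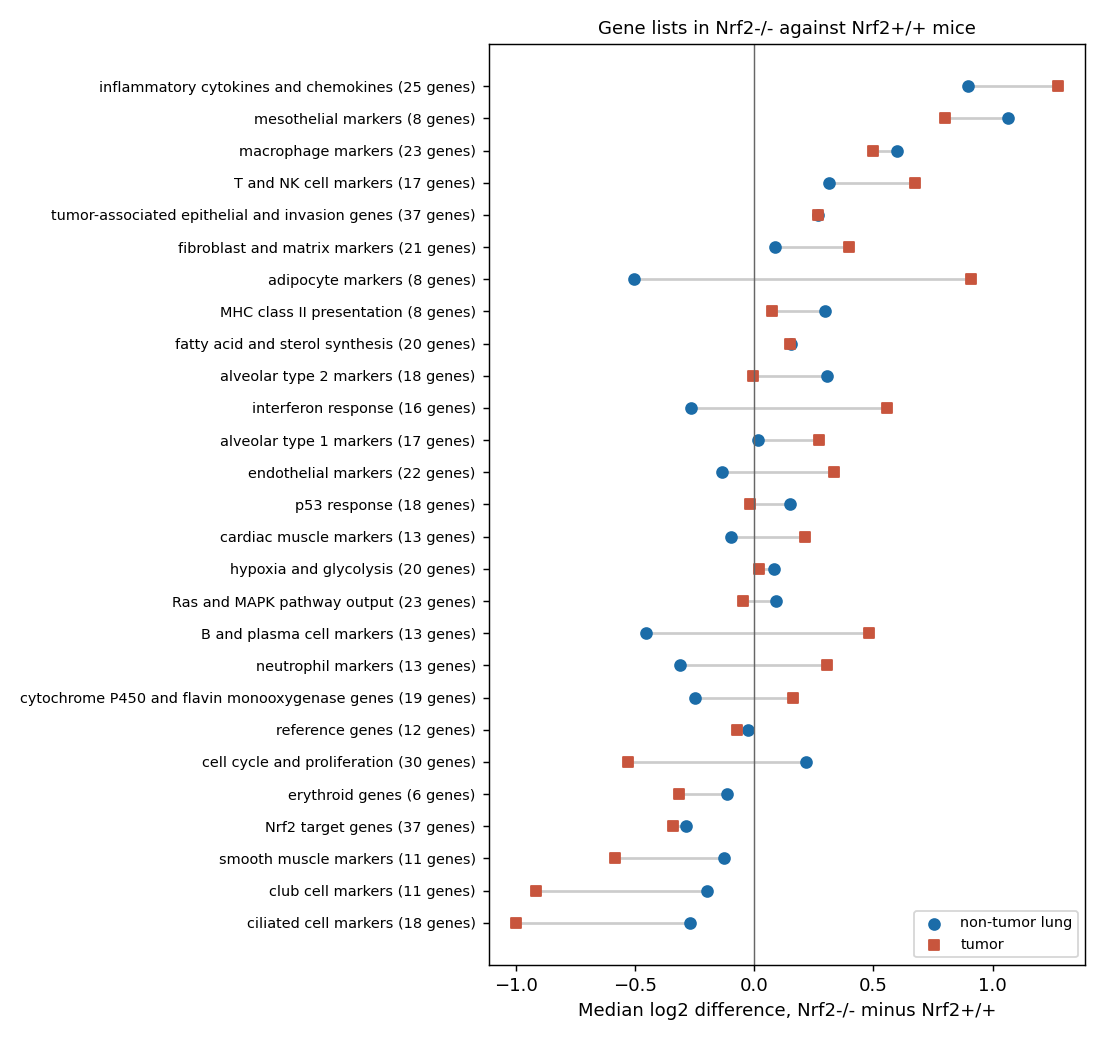
Median log2 difference, Nrf2-/- minus Nrf2+/+, of each gene list on the horizontal axis, with a point for non-tumor lung and a point for tumor and 1 array per group. Inflammatory cytokines and chemokines stand at 0.89 in non-tumor lung and 1.28 in tumor and Nrf2 target genes at -0.29 and -0.34, whereas cell cycle genes stand at 0.22 and -0.53.

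Genotype differences were compared between the tissues, again without a shared array. Among genes with a symbol that were well above background on all 4 arrays, those higher in Nrf2-/- mice in both tissues by the widest margin were Pitrm1 (3.01 in non-tumor lung and 3.07 in tumor), Ly6k (2.75 and 2.78), Camk2n1 (2.87 and 2.69), Pigs (3.21 and 2.58), Slc26a4, the anion exchanger pendrin (2.53 and 2.68), Wfdc21 (2.42 and 3.32), Prg4 (2.88 and 2.39) and Ly6f (2.28 and 3.73). The lowest of these in both were Rmnd1 (-4.37 and -4.55), Firre (-3.99 and -4.43), C3 (-3.60 and -3.95), Ifi47 (-4.25 and -3.32), Adi1 (-2.71 and -2.74), Tpd52l2 (-2.33 and -2.47), the platelet chemokine Ppbp (-2.42 and -2.16) and Gpx2 (-2.08 and -2.93). The other probe of Pigs averaged 0.20 over the 2 tissues, against 2.90 for the probe used. Over 17461 genes, 170 were higher and 203 lower past 2-fold in both tissues (12.8 and 13.5 if independent) and 23 went opposite ways (26.9 if independent). The counts higher and lower in both were 77 and 82 with normexp and 111 and 104 with the filter on every array. Pearson's r across the 16287 genes on all 4 arrays was 0.43 and Spearman's rho 0.28.

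The last comparison asked whether the tumor difference itself depended on genotype. It was higher in Nrf2-/- mice by 5.69 for Ubd, 4.80 for Ptprn, 4.07 for Ly6d, 3.46 for Fga and 3.37 for Ido1, and it was lower for Xlr3c (-4.32), Cxcl5 (-4.03), the secreted peptide gene Ecrg4 (-3.15), Cckar (-3.06) and the oncogene Mycn (-2.89). The median of this difference of differences was 1.74 for adipocyte markers, 1.00 for B and plasma cell markers, 0.94 for neutrophil markers, 0.83 for interferon genes, 0.52 for T and NK cell markers, 0.43 for endothelial markers, 0.34 for cardiac markers, 0.26 for cytokines, 0.21 for type 1 markers, 0.17 for fibroblast markers, -0.30 for smooth muscle markers, -0.66 for cell cycle genes, -0.69 for ciliated markers and -0.72 for club cell markers. With the macrophage (0.12) and fatty acid (0.09) lists, whose medians became -0.040 and -0.065 with median scaling, these were the lists outside the central 95% of random lists. The cardiac, fibroblast, smooth muscle, macrophage and fatty acid lists each came within it under at least 1 other setting. Of the 8 measured adipocyte markers, 4 were well above background on all 4 arrays, too few for the repeat over such genes. The difference of differences was at least 2-fold for 1399 genes in the higher direction and 819 in the lower of 20553. The counts were 1145 and 1038 with quantile normalization, but 1078 and 1102 with median scaling, which moved its median over all genes by -0.16. Over genes on all 4 arrays the counts were 434 and 269. The design leaves no degrees of freedom for a test of it, and because the Nrf2+/+ non-tumor array was alone on its slide, it cannot be told apart from a slide difference.

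The only test the design allowed was an additive fit with limma, in which tissue and genotype each had a term and the spread came from a single residual degree of freedom per gene. No gene reached an adjusted p under 0.05 over all 20553 tested, for tissue or for genotype. On simulated data with the spread of these genes the fit recovered 0 of the genes changed by up to 3 on the log2 scale. The absence of calls therefore cannot show an absence of differences. At an unadjusted p under 0.05 there were 2425 higher and 3670 lower genes for tumor and 985 and 925 for Nrf2-/-. Restricted to the 16287 genes well above background on all 4 arrays, the fit called 1766 higher and 2086 lower in tumor and 73 higher and 77 lower in Nrf2-/- mice. In simulation this restricted fit made more false calls than the threshold allows, 14 per run for tissue and 13.6 for genotype. Adjusted over the list alone, 14 type 2 markers were called higher and 1 lower in tumor, 1 type 1 marker higher and 12 lower, 17 of 18 ciliated and 20 of 22 endothelial markers lower, 11 cardiac, 9 smooth muscle and 8 mesothelial markers lower, and 11 Ras and MAPK genes higher and 1 lower, beside 0 of each over all genes. Nrf2 targets gave 11 higher and 6 lower for tumor and 0 higher and 6 lower for Nrf2-/- adjusted over the list alone. Cytokines and mesothelial markers gave 4 higher each for Nrf2-/- adjusted over the list alone, and cell cycle genes gave 0 for either term. In the fit over the 16287 genes, 13 of 29 cell cycle genes were called higher in tumor adjusted over the list alone (9 over all genes) and 0 for genotype, 12 of 19 cytokines were called higher for Nrf2-/- (4 over all genes), and 11 of 32 Nrf2 targets lower (5 over all genes). Over all genes it also called 14 type 2 markers and 10 Ras and MAPK genes higher in tumor and 11 type 1, 11 ciliated, 19 endothelial, 8 smooth muscle and 6 mesothelial markers lower. The spread of this fit is the genotype-by-tissue difference and not that between animals. Of the 3 ways to split 4 arrays into pairs, tumor against non-tumor put 3609 genes past 2-fold, Nrf2-/- against Nrf2+/+ 1435 and the remaining split 763.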

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

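All tests in this part were chosen after the results were seen, and the differences between groups listed here were not tested, since each group had 1 array. Opposite directions singled these results out: 39 genes were past 2-fold one way in Nrf2+/+ tumors and the other way in Nrf2-/- tumors, and 23 genes were past 2-fold one way between genotypes in non-tumor lung and the other way in tumor. The median genotype difference in tumor less that in non-tumor lung was -0.75 for cell cycle genes, 0.47 for endothelial markers, 0.94 for B and plasma cell markers, 0.62 for neutrophil markers, 0.82 for interferon response genes and 1.41 for adipocyte markers, and each list's medians had opposite signs in the 2 tissues. For endothelial markers the sign in non-tumor lung turned with median scaling (0.0096 in place of -0.13). Of the 8 measured adipocyte markers, 4 were well above background on all 4 arrays. Cxcl5 had a tumor difference of 2.85 in Nrf2+/+ and -1.18 in Nrf2-/- mice and a genotype difference of 2.03 in non-tumor lung and -2.0 in tumor, so that its difference of differences was -4.03. The genotype difference of Nppa was -1.06 in non-tumor lung and at least 5.75 in tumor, where it was not well above background in Nrf2+/+ mice (at least 6.81 apart), that of Ubd -2.30 and 3.39 (5.69 apart), and that of Xlr3c 2.44 and -1.87 (-4.32 apart). The non-tumor values come from arrays on different slides.

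The first pattern was the set of genotype differences that both tissues shared. A slide effect alone is argued against by the 373 genes past 2-fold the same way in both tissues, where independent lists would share 26.3, since the tumor comparison lay within a slide. Neighbours of the disrupted gene are argued against as the whole cause: 6 of 232 placed genes (2.59%) lay within 200 gene positions of Nfe2l2, where 2.90 would if they were spread evenly, and these were Crb2, Lhx2, Kif5c, Lypd6b, Chrna1 and Cwc22. Strain variants under single probes are also argued against as the whole cause. Of 55 other probes, which belong to 44 of the 373 genes, 76.4% showed at least 50% of the difference. The other probe of Nfe2l2, the disrupted gene, is among them, and some genes gave several probes. Strain variants may account for part, because 18.2% of the probes showed under 25% of the difference, against 2.97% for the shared tumor differences. The probes under 25% belonged to 9 of the 44 genes, with Pigs, Nptn, Dnajc5, Hspa13 and H2-DMb1 among these genes. Genes with a single usable probe were not tested in this way. The absence of Nrf2 and a difference in genetic background between the mouse lines stay open and were not tested.

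The second pattern was lower cell cycle genes together with higher cytokine, interferon and lymphocyte genes in Nrf2-/- tumors than in Nrf2+/+ tumors. Both tumor arrays lay on slide 2, so a difference between slides does not enter this comparison, in which the cell cycle median was -0.53. Fewer tumor cells in the Nrf2-/- tumor RNA would raise the markers of all other cell types, if those kept their proportions in non-tumor lung. Mesothelial (0.80), fibroblast (0.40), endothelial (0.34) and type 1 (0.27) medians, among others, were higher. Ciliated (-1.0), club cell (-0.91), smooth muscle (-0.58) and erythroid (-0.32) medians were lower. These values argue against such an even dilution only. A smaller tumor share beside other cells in changed proportions was not tested and stays open. A difference between the arrays within the slide, a larger share of leukocytes and a genotype effect within tumor cells stay open and were not tested.

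The third pattern was Nppa, which was higher by 5.98 in Nrf2-/- tumor than in Nrf2-/- non-tumor lung. Heart muscle carried into the tumor RNA is argued against as the source of this difference. The other 12 cardiac markers had a median of -2.39, 11 of them at least 2-fold lower and the highest at -0.17. Between the tumor arrays, 4 of 13 cardiac markers, Nppa among them, were at least 2-fold higher in Nrf2-/- mice and 0 lower (median 0.21). A smaller amount of muscle in that pool is therefore not excluded. Expression of Nppa in the tumor itself, in a few tumors of the pool or in most, stays open and was not tested.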

How the results depend on the processing

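Scaling on spike-in probes was chosen after seeing the data; every other alternative was planned. Quantile normalization, the mean of all probes of a gene and the submitters' value table left all 18 counts within 1.5 times the main value. The submitters' table repeats the main signal within rounding, so its counts were bound to stay. The 18 include the counts of the additive fit, which were 0 in each of these settings. Of the 98 list medians that stood apart from matched random lists, 659 of 682 repeats stood apart in the same direction, 22 no longer did, and 1 turned: the cardiac list's difference of differences was -0.014 relative to random lists when only genes on all 4 arrays were used, a list of fewer genes. Of the list medians that did not stand apart, 11 of 258 repeats did. Median and spike-in scaling shift a list and its random lists alike, so their repeats could not change beyond the random draw. The submitters' table repeats the main signal within rounding. In each of these settings all 98 stood apart in the same direction, so these repeats say nothing about stability. For the genes named here, the shift of all genes was subtracted first, and no difference past 2-fold turned. Of 2430 repeats, 354 moved by more than the measurement error, 275 of them with normexp, where 130 did not. After that subtraction median and spike-in scaling return the main value, and the submitters' table repeats the main signal. All 405 repeats in each of these settings were therefore bound to stay. The 3-fold mark and the stricter filter lower the 2-fold counts by construction, and dropping the filter raises them by construction. The offset of 50 in normexp shrinks the differences of dim genes by construction. How much of the lower normexp counts comes from it was not tested. For the other settings the cause was not tested. No paired analysis was possible because each group had 1 array and the arrays' numbers tie no samples together. The fit with slide as a block was not run, since no residual degree of freedom is left. Signal over background limits what can be read: about 54% to 63% of spots were well above it, and a gene below it on an array has only a bound there.

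With normexp, 1198 genes were lower in Nrf2+/+ tumor and 519 lower in Nrf2-/- tumor, 204 higher and 255 lower in Nrf2-/- non-tumor lung, 364 higher and 236 lower in Nrf2-/- tumor than in Nrf2+/+ tumor, 431 lower in tumors of both genotypes, 77 higher and 82 lower in Nrf2-/- in both tissues, and 377 and 245 for the difference of differences. Median scaling gave 2633 higher in Nrf2+/+ tumor. Spike-in scaling gave 2788 lower in Nrf2-/- tumor and 404 higher and 1995 lower in tumors of both genotypes. The filter on every array gave 1792 lower in Nrf2+/+ tumor, 872 lower in Nrf2-/- tumor, 328 higher and 465 lower for genotype in non-tumor lung, 460 and 307 for genotype in tumor, 741 lower in tumors of both genotypes, 111 higher and 104 lower in Nrf2-/- in both tissues, and 434 and 269 for the difference of differences. With no filter, 1639 genes were higher in Nrf2-/- tumor, 1589 lower for genotype in non-tumor lung, 1249 higher for genotype in tumor and 2682 higher for the difference of differences. At 3-fold the counts were 698 higher and 1422 lower in Nrf2+/+ tumor, 560 and 730 in Nrf2-/- tumor, 301 and 432 for genotype in non-tumor lung, 387 and 347 for genotype in tumor, 264 and 420 in tumors of both genotypes, 57 and 81 for genotype in both tissues, and 650 and 407 for the difference of differences.

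The additive limma fit, with 0 calls in the main setting, called 1525 higher and 1670 lower for tumor with normexp, 1076 and 1079 with median scaling, 491 and 2527 with spike-in scaling, 1766 and 2086 for genes on every array, 293 and 476 with no filter, 2138 and 2484 with an intensity trend, and 9 higher without the genotype term. For genotype it called 26 higher and 28 lower with normexp, 37 and 41 with median scaling, 73 and 77 for genes on every array, 124 and 116 with an intensity trend, and 1 lower each with spike-in scaling and with no filter. Leaving out each array in turn, with the other factor dropped and the lone array assumed to vary like the others, gave from 0 to 0 calls for every term.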

Other observations

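No test in this part was chosen after its result was seen. Members of the lipid synthesis and p53 response lists are described here. Of 20 fatty acid and sterol synthesis genes, 4 were at least 2-fold higher in Nrf2+/+ tumors (median 0.32, within the central 95% of random lists) and 5 in Nrf2-/- tumors (median 0.39, above it), and none was 2-fold lower in either. Those higher in both genotypes were Me1, which supplies NADPH (2.34 and 2.42), Acsl4, an acyl-CoA synthetase (1.35 and 1.18), Elovl1 (1.38 and 1.22) and Fasn, the fatty acid synthase (1.21 and 1.06), whereas Scd1 stood at 0.70 and 1.45. Between genotypes the list's median was 0.16 in non-tumor lung (none higher, 1 lower), within the central 95% of random lists, and 0.15 in tumor (1 higher, 1 lower), above it. The sterol gene Fdps was the member higher in tumor, at 1.02, and Me1, also in the Nrf2 target list, the member lower in both tissues. Adjusted over the list alone, limma's additive fit called 4 of these genes higher in tumor and 0 over all genes.

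Among 18 p53 response genes, 5 were at least 2-fold higher and 1 lower in Nrf2+/+ tumors (median 0.36) and none was past 2-fold in Nrf2-/- tumors (median 0.16, which became -0.13 with spike-in scaling); all 4 medians of this list lay within the central 95% of random lists, those between genotypes being 0.15 in non-tumor lung and -0.02 in tumor. Plk2, a kinase induced by stress, stood at 1.74 in Nrf2+/+ and 0.16 in Nrf2-/- tumors, Perp, a desmosome protein, at 1.14 and 0.21, Gdf15 at 1.37 and 1.00, and Cdkn1a, the cell cycle inhibitor p21, at 0.12 and 0.16. Cdkn2a was at least 12.9-fold higher in Nrf2+/+ tumor than in Nrf2+/+ non-tumor lung and stood at 0.05 between the Nrf2-/- tissues. With Cxcl1, Cxcl3 and Mmp12, a macrophage elastase, it was measured on 3 arrays and not well above background in Nrf2+/+ non-tumor lung, the array on a slide of its own; these 4 genes were grouped after their values were seen.

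Of the genes well above background on at least 1 of the 2 tumor arrays, 7.96% were past 2-fold between Nrf2-/- and Nrf2+/+ tumors. List members were counted under the wider filter of at least 1 of the 4 arrays. Within the leukocyte lists, some members were past 2-fold. These were 3 of 13 B and plasma cell, 3 of 13 neutrophil and 1 of 17 T and NK cell markers, all higher. Macrophage markers had 4 higher and 1 lower of 23. Fcer2a, a low-affinity IgE receptor of B cells, was higher by 2.57, Jchain, the joining chain of secreted antibodies, by 2.18 and Tnfrsf17, a receptor of plasma cells, by 1.08, while Cd79a stood at 0.16. Of the neutrophil markers, Ltf (1.72), Mmp9 (1.71) and Cxcr2 (1.57) were higher and S100a8 stood at -0.07. Of the T and NK cell markers, Cd8a was higher by 1.09, with Cd247 at 0.99 and Gzmb at 0.34. Of the macrophage markers, Spp1 (1.82), Marco (1.44), Ctsk (1.09) and Fabp1 (1.00) were higher and Arg1 was lower (-1.33).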
